A study of Sus scrofa with 9 samples.

How the data were processed

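Small RNA of 10 to 40 nt from the longissimus dorsi of female Jinhua pigs was size selected on a polyacrylamide gel and sequenced on an Illumina Genome Analyzer II, per the labels. The 9 libraries were grouped by the age in their labels as E90, day 0, day 30 (1 library each), day 180 and 7 years (3 libraries each). The deposited tables give counts, the whole number of copies of each miRNA in each library, per the file headers, together with the most abundant sequence of each miRNA in each library and its length. The file headers also give the high-quality reads of each library, from 3476614 to 12259667, and place the precursors on the pig assembly Sscrofa10. The aligner, the program that called the miRNAs, the rules for calling and the annotation are not given in the sources used here. No count was normalised before deposit, as far as the whole numbers and differing totals show.

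The conserved table held 100 miRNA arms and the table of putative new miRNAs 426. A few other lines without values are not reported here. An arm is the product of the 5p or the 3p side of a precursor hairpin. Of 900 conserved cells, 416 were empty (46.2%), and of 3834 putative new cells, 2919 (76.1%). No cell held a written 0 and only 5 held a value under 3, so an empty cell may stand for up to about 2 copies. Empty cells were counted as 0 in the main tests. Putative new arms with the same sequence and the same values were merged, which left 395. The interval given for a precursor was the precursor itself in the conserved table (median 92 bp) and a longer stretch in the putative new table (median 262 bp). For 32 conserved and 112 putative new arms, among them most of the DLK1-DIO3 cluster, the chromosome field named no chromosome, and no coordinates are printed for them. A reference of another assembly was at hand and was not used for coordinates.

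The copies of both tables together were 2.70% of the high-quality reads at E90, 1.92% at day 0, 1.04% at day 30, 0.324%, 0.259% and 0.279% at day 180, and 0.197%, 0.162% and 0.148% at 7 years. The remaining reads were not analysed here, and whether miRNAs already known in the pig are among them is not given in the sources used here, so the tables hold part of each library, and the high-quality reads of the header were taken as library size. A floor of 3 copies per library corresponds to 0.595 RPM (copies per 1000000 high-quality reads) at E90, 0.671 at day 0 and 0.863 at day 30. It corresponds to 0.245, 0.288 and 0.332 at day 180 and to 0.481, 0.806 and 0.320 at 7 years. Folds against a stage in which no library listed an arm are lower bounds in RPM, without a TMM factor, against the mean of these floors. Counting intervals are exact 95% intervals. They and the floors cover counting error only, since reads are not independent molecules. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom from 14.6 to 38.1 and correlations of log2 copies across arms from 0.716 to 0.855, so none was a second copy of another.

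Differences between stages were tested with edgeR 4.0.16 in R 4.3.3. Factors were TMM on the high-quality reads, the filter was filterByExpr (minimum count 10, minimum total 15), dispersion and the quasi-likelihood fit were robust, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All 9 libraries entered a fit with a term per stage, from which 7 years, E90, day 0 and day 30 were each contrasted with day 180 over 175 arms. In this fit the single libraries are assumed to vary like those of day 180 and 7 years. A fit with 2 groups set E90, day 0 and day 30 (3 libraries) against day 180 and 7 years (6 libraries) over 91 arms. TMM factors went from 0.375 in 7 years replicate 2 to 4.25 at E90 in the fit with a term per stage, and from 0.516 in 7 years replicate 3 to 2.71 at day 0 in the fit with 2 groups, so that a call is a change relative to the bulk of tested arms and not per read. Standard errors are the absolute log2 fold change divided by the root of the F statistic. Sums and shares were compared by two-sided exact permutation tests (scipy 1.17.1). For early against later libraries these tests take libraries as exchangeable. The later ones are replicates of only day 180 and 7 years, and each early one is of another age. Ratios between single libraries carry a counting interval and no test, and cover conserved arms with at least 100 copies in either library. Groups of neighbouring precursors were formed with gaps of up to 10 kb. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

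The edgeR comparisons, the named miRNAs' rule and the alternatives listed first below were fixed before the data were examined. So were the permutation tests of the shares of the 10 most abundant arms and of the myomiR list. Camera was fixed for 7 years against day 180 and for the 2-group comparison. Permutation tests of sums and camera for E90, day 0 and day 30 against day 180 were not fixed in advance. Lists of miRNAs were also fixed before the data were examined. They were myomiR (8 members, 2 measured), other myogenesis (20, 0 measured), let-7 (9, 0), DLK1-DIO3 (44, 13), miR-17-92 (13, 0), blood (5, 1), vessel and connective tissue (7, 0), epithelial and neural (13, 4), inflammation and ageing (6, 1) and miR-30 (5, 0). Lists with at least 3 tested arms were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. Named miRNAs are the 10 largest rises and 10 largest falls per comparison among called conserved arms with a mean of at least 10 RPM, and the 3 largest each way among called putative new arms. They also include the myomiR members, the 4 most abundant members of every other list, the 10 most abundant arms over all libraries and, for ratios between single libraries, the 6 largest each way. miR-188-5p, miR-301a-3p, miR-1983-3p, miR-1a-2-5p, PN-3335108-5p, PN-151102661-5p, PN-151102665-5p, PN-868884-3p and, at 7 years, miR-411c-3p and miR-412-5p are named in part on what their values showed.

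The test was checked on simulated counts with each arm's mean over all 9 libraries and with library sizes scaled by TMM, with 40 changed arms in each of 20 runs. An arm higher in the early libraries was thus simulated above its level at day 180 and 7 years. No low simulated count was emptied, unlike in the data, so the rates below hold for that setting only. For 7 years against day 180 (175 arms) it called 1.13% of 2-fold, 9.41% of 4-fold and 18.95% of 8-fold changes, and 7.23% of its calls were of unchanged arms. For the 2-group comparison (91 arms) it called 1.52%, 13.1% and 39.4% of 2-, 4- and 8-fold changes, with 2.11% of calls of unchanged arms. For E90 against day 180 (175 arms) it called 1.78%, 3.75% and 13.5%, with 12.5% of calls of unchanged arms, so most changes of these sizes would not be called.

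The alternatives fixed in advance were DESeq2 size factors in the edgeR fit, total reads without a factor, the Wald test of DESeq2 1.42.0, no filter, a filter of a mean of at least 10 RPM, conserved arms alone, every arm kept, each library left out, the replicate number as a block, the 6 libraries of day 180 and 7 years alone, a term per stage for the 2-group comparison, and other denominators. Alternatives chosen after seeing the data set empty cells to 2 copies, joined putative new arms that share a stretch of 16 bases (426 arms in 312 groups, with TMM and, for the 2-group comparison, also with total reads), ranked the 10 most abundant arms within each library, left miR-431-5p out of the DLK1-DIO3 list, added miR-1a-2-5p to the myomiR list, and took sums without single libraries or without the 10 most abundant arms. Alternatives for normalised values did not apply to counts.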

Results

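Small RNA was sequenced from the longissimus dorsi, the long muscle of the back, of female pigs of the Jinhua breed at 5 stages, to follow microRNAs (miRNAs) through muscle development and ageing. The stages were fetuses at day 90 of gestation (E90), newborn pigs (day 0), and pigs at day 30, day 180 and 7 years of age. E90, day 0 and day 30 had 1 library each, and day 180 and 7 years had 3 libraries each, from 15 pigs in all. How pigs were spread over the 9 libraries is not given in the sources used here, so p-values measure only the spread between libraries, which may be technical. Libraries held 5042191 high-quality reads at E90, 4469677 at day 0 and 3476614 at day 30. The day 180 libraries held 12259667, 10435597 and 9024703 reads, and those of 7 years 6239845, 3720989 and 9389375. The measurement was the number of copies of 100 conserved miRNAs, which carry the names of known families, and of 426 putative new miRNAs, here named PN with the start of their precursor. Levels are in RPM, copies per 1000000 high-quality reads of the library. Whether miRNAs already known in the pig were kept elsewhere is not given in the sources used here, so sums and shares describe these tables and not all miRNAs of the muscle. The muscle-enriched miR-133 and miR-206 and the let-7 family had no measured member in these tables and were not analysed here.

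The summed level of the measured conserved miRNAs was highest in the fetus and lowest in the oldest animals. Their summed RPM values were 23512 at E90, 16747 at day 0, 9155 at day 30, 2244 ± 254 (SD, n = 3) at day 180 and 1352 ± 212 (SD, n = 3) at 7 years. The putative new miRNAs went from 3496 at E90 to 2412 at day 0, 1279 at day 30, 628 ± 90.7 (SD, n = 3) at day 180 and 335 ± 42.6 (SD, n = 3) at 7 years. Measured members of the imprinted DLK1-DIO3 cluster, a large group of miRNAs expressed from the maternal chromosome, summed to 14310 at E90 and 7327 at day 0. They summed to 4968 at day 30, 772 ± 128 (SD, n = 3) at day 180 and 222 ± 42.4 (SD, n = 3) at 7 years, so that E90 exceeded 7 years 64.5-fold. In 7 years replicates 2 and 3 the most abundant sequence listed for miR-431-5p, a member with a large part of this sum, did not match its precursor. Without miR-431-5p in any library the list summed to 9783 at E90, 151 ± 38.8 (SD, n = 3) at day 180 and 63.7 ± 13.2 (SD, n = 3) at 7 years, and E90 exceeded 7 years 154-fold. The full list is part of the conserved sum. Outside the full list the conserved copies were not higher at E90 than at day 0. A pair of X-linked precursors, mir-188 and mir-660 (Sscrofa10, X, 48632378 to 48640903), summed to 1473 at E90, 852 at day 0, 275 at day 30, 104 ± 35 (SD, n = 3) at day 180 and 4.35 ± 0.426 (SD, n = 3) at 7 years.

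Each of these 4 sums was higher in every one of the 3 libraries up to day 30 than in every one of the 6 later ones. The DLK1-DIO3 list and the X-linked pair are parts of the conserved sum, so the 4 sums are not independent. The two-sided exact permutation p was 0.0119, the smallest that 84 splits allow (adjusted p = 0.0417 over 14 relations of table and list sums, for the first 3 of these). This test of sums was not fixed in advance. It counts replicates of day 180 and of 7 years as separate units, so its p does not measure the spread between ages. Each of the 4 sums was also lower in all 3 libraries of 7 years than in all 3 of day 180, with an exact p of 0.1, the smallest possible for 3 against 3 (adjusted p = 0.156 for the first 3). The X-linked pair and the chromosome 6 block described next were picked after their values were seen, among 8 groups of neighbouring precursors, and their p-values are not adjusted. By contrast, 5 precursors within 4313 bp of chromosome 6 (Sscrofa10, 866649 to 870961), among them mir-716a and mir-5105, summed to 50.0 at E90, 128 at day 0, 88.9 at day 30, 138 ± 41.6 (SD, n = 3) at day 180 and 72.0 ± 33.5 (SD, n = 3) at 7 years. The exact permutation p of this block was 0.631 for the libraries up to day 30 against the later ones. It was 0.1 for 7 years against day 180, where the libraries of 7 years were the lower ones. Of the most abundant sequences of this block 43.0% were 20 to 24 nt long, against 94.1% of those of the other conserved miRNAs.

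**Figure D1:**
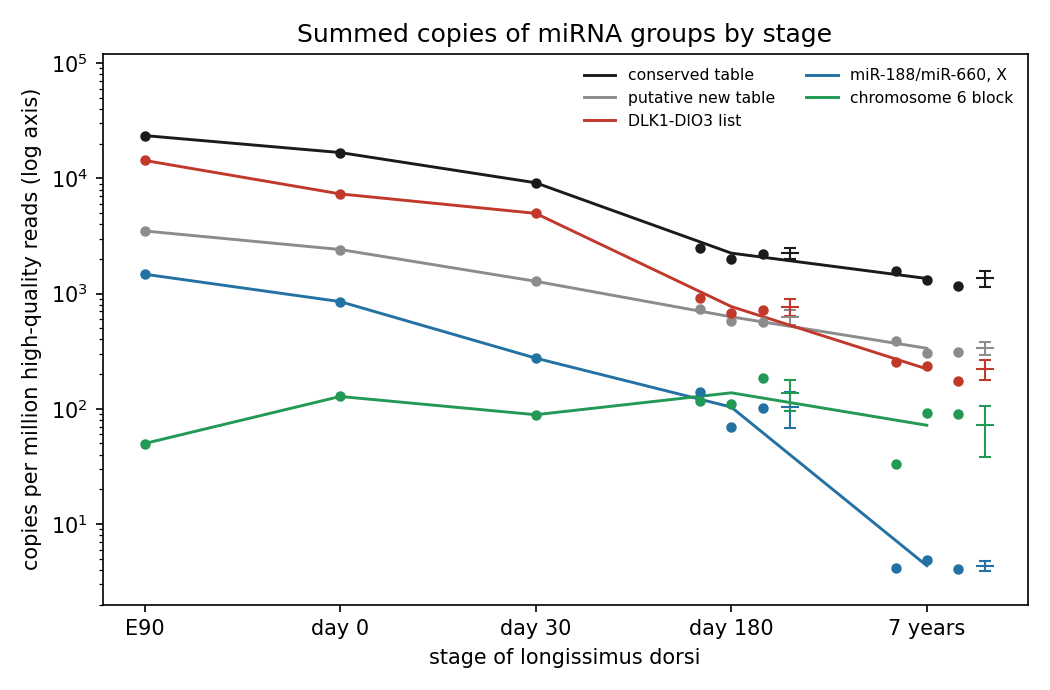
Summed RPM (log axis) of the conserved table, the putative new table, the DLK1-DIO3 list, the X-linked pair and the chromosome 6 block at each stage. Points are libraries, lines join stage means, and bars beside day 180 and 7 years are mean ± SD over 3 libraries. The conserved sum goes from 23512 at E90 to 1352 at 7 years, and the chromosome 6 block lies between 33.3 and 185 in all 9 libraries.

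The comparison of 7 years with day 180, the only one with replicates at both ages, asks which miRNAs differ between young adult and aged muscle. Relative to the other miRNAs, 6 fell and none rose at 7 years among 175 tested (edgeR quasi-likelihood test, adjusted p under 0.05). miR-409-3p of the DLK1-DIO3 cluster was at 21 ± 6.79 RPM (SD, n = 3) at day 180 and listed in none of the 3 libraries of 7 years. With a floor of 3 copies per library it was at least 39.2-fold lower (edgeR adjusted p = 7.7e-05). miR-660-5p (X, 48640809 to 48640903, plus strand) fell from 102 ± 34.8 to 4.35 ± 0.426 (log2 fold change −3.62, SE 0.30, edgeR adjusted p = 7.7e-05). miR-431-5p (chromosome 7, 132097559 to 132097659, plus strand), also of the DLK1-DIO3 cluster, fell from 621 ± 91.1 to 158 ± 41.5 (log2 fold change −1.06, SE 0.23, edgeR adjusted p = 0.0417).

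The other 3 calls were low at day 180 and listed in no library of 7 years. miR-485-3p was at 1.26 ± 0.431 RPM at day 180 (at least 2.36-fold lower at 7 years, edgeR adjusted p = 0.0116). miR-411c-3p was at 1.35 ± 0.596 (at least 2.52-fold lower, edgeR adjusted p = 0.0147) and miR-412-5p at 1.77 ± 1.54 (at least 3.30-fold lower, edgeR adjusted p = 0.0417). In the DLK1-DIO3 list, 4 of 19 tested arms fell (6 when adjusted over the list alone), none rose and 15 were not called. limma camera placed the list below the other miRNAs (adjusted p = 0.0392 over 2 lists), with an adjusted p = 0.141 under an estimated correlation and an adjusted p = 0.0962 without miR-431-5p in the list. The most abundant miRNA of the tables, miR-26b-5p, was at 715 ± 82.1 RPM at day 180 and 542 ± 114 at 7 years (edgeR adjusted p = 0.217). miR-411c-5p was at 375 ± 48.1 and 462 ± 176 (edgeR adjusted p = 0.115), and was called higher by DESeq2's Wald test (log2 fold change 1.18, adjusted p = 0.0175), without a filter on abundance (0.00510), with a stricter one (0.0345) and without 7 years replicate 3 (0.0231). miR-655-3p was at 16.2 ± 0.229 and 8.63 ± 0.831, miR-544-5p at 53.3 ± 16.2 and 26.5 ± 6.67, and miR-539-3p at 31.1 ± 5.20 and 20.7 ± 5.75 (edgeR adjusted p = 1, 1 and 0.699). Scaling by total reads in place of TMM, a scaling by the bulk of miRNAs, shifted log2 fold changes by −0.90, which turned the sign of miR-26b-5p and miR-539-3p, and called 14 lower and none higher.

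In all, 22 of the 175 had an unadjusted p under 0.05. Calls numbered 2 without day 180 replicate 1, without day 180 replicate 3 or without 7 years replicate 2, where miR-431-5p (adjusted p from 0.0535 to 0.273), miR-485-3p (from 0.0535 to 0.121), miR-411c-3p (from 0.0535 to 0.121) and miR-412-5p (from 0.152 to 0.207) were lost. miR-412-5p was also lost without 7 years replicate 1 (0.145) or 3 (0.168), and miR-431-5p without 7 years replicate 1 (0.145), with DESeq2 size factors (0.0934), with conserved miRNAs alone (0.141) and with the 6 libraries of these ages alone (0.0826). In 7 years replicates 2 and 3 the most abundant sequence listed for miR-431-5p shared only 4 nt with its precursor, and with empty cells set to 2 copies, a choice made after seeing the data, miR-485-3p, miR-411c-3p and miR-412-5p were no longer called.

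Libraries up to day 30 were then set against those of day 180 and later, to ask what separates developing from adult muscle. Replicates of day 180 and of 7 years counted as separate units, and every early stage had a single library. The split thus also sets stages without replicates against stages with them. Of 91 miRNAs tested, 35 were higher and 19 lower in the early libraries (edgeR, adjusted p under 0.05). The higher ones were 23 conserved and 12 putative new miRNAs, the lower ones 4 conserved and 15 putative new. Some of the putative new ones are overlapping entries and no separate changes, as described below. The higher group held 13 arms of the DLK1-DIO3 list. miR-655-3p stood at 1422 RPM against 12.4 (mean of 3 and of 6 libraries, log2 fold change 5.01, SE 0.39, edgeR adjusted p = 3.4e-06). miR-485-3p stood at 386 against 0.631 (log2 fold change 7.43, SE 1.26), miR-412-5p at 252 against 0.884 (6.42, SE 1.37), miR-409-3p at 1797 against 10.5 (5.77, SE 1.85), miR-431-5p at 3822 against 390 (1.61, SE 0.45), and miR-539-3p at 317 against 25.9 (1.85, SE 0.60). In this list 13 of 14 tested arms were higher (14 when adjusted over the list alone) and none lower. limma camera gave p = 0.000276 for the list, and p = 0.134 with an estimated correlation.

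Of miRNA families of the DLK1-DIO3 cluster, some members that the list does not hold were called as well. miR-376d-3p was higher at 169 against 0.144 RPM (log2 fold change 8.10, SE 0.97) and miR-411c-3p at 183 against 0.676 (6.44, SE 1.10). miR-411c-5p, of the same precursor as miR-411c-3p, was lower (−4.03, SE 0.56). Outside this group, miR-188-5p of the X-linked pair stood at 42.2 against 0.537 (log2 fold change 4.56, SE 1.07, edgeR adjusted p = 0.00431), and its neighbour miR-660-5p had a log2 fold change of 2.27 (SE 0.98) without a call (edgeR adjusted p = 0.0655). miR-660-5p was called higher with a term per stage (log2 fold change 2.45, edgeR adjusted p = 4.5e-05), DESeq2 size factors (0.0159), total reads (0.0114) and without day 180 replicate 1 (0.0339). miR-26b-5p stood at 5728 against 629 (log2 fold change 1.32, SE 0.28, edgeR adjusted p = 0.00291). Among putative new miRNAs, PN-32286946-5p (chromosome 14, 32286946 to 32287205, plus strand) was listed at 39.9, 50.3 and 14.7 RPM at E90, day 0 and day 30 and in none of the 6 later libraries. Entries of the same locus that share at least 16 bases with it were listed with 17, 9 and 4 copies in day 180 replicates 1, 2 and 3 and in no library of 7 years. At E90 it was at least 74.4-fold above 7 years.

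The lower group held miR-411c-5p, at 87.8 RPM in the early libraries against 419 in the later ones (log2 fold change −4.03, SE 0.56, edgeR adjusted p = 0.000297), opposite in sign to the other arm of its precursor. miR-716a-3p (chromosome 6, 868791 to 868939, minus strand) stood at 8.09 against 29.3 (−3.57, SE 0.75) and miR-5105-3p (chromosome 6, 870882 to 870961, minus strand) at 15.5 against 47.3 (−3.39, SE 0.59), both of the chromosome 6 block. PN-7444591-3p (chromosome 2, 7444591 to 7444852, minus strand) stood at 5.12 against 103 (−6.00, SE 0.74, edgeR adjusted p = 0.000117). miR-301a-3p, listed in no early library, was lower with 10.6 RPM later, where 3 of the 6 libraries did not list it either, among them day 180 replicate 3, for which the other replicates predicted 259 copies. It was not called with total reads (edgeR adjusted p = 0.0502). Of the blood marker miR-223-3p and the epithelial marker miR-141-3p neither was called (edgeR adjusted p = 0.126 and 0.556). miR-223-3p was called lower in the early libraries with conserved miRNAs alone (0.0181) and with empty cells set to 2 copies (0.0197), and miR-141-3p higher with total reads (0.0171).

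Scaling by total reads shifted log2 fold changes by 1.80 and called 48 higher and 11 lower, with 46 calls shared by both scalings. Calls numbered 24 with a stricter filter on abundance and 22 with conserved miRNAs alone, settings in which miR-26b-5p, miR-431-5p and miR-539-3p were no longer called. Without a filter they numbered 71, of which 38 were among the 54, and the calls of miR-409-3p (edgeR adjusted p = 0.143), miR-26b-5p (0.143) and miR-539-3p (0.0798) ended. That of miR-539-3p also ended with a term per stage (0.0709) and that of miR-26b-5p with empty cells set to 2 copies (0.055). Leaving out the only library of day 0 ended the calls of miR-26b-5p (edgeR adjusted p = 0.12) and miR-539-3p (0.171), the only library of day 30 that of miR-539-3p (0.109), and the only library of E90 or of day 30 that of miR-409-3p (0.138 and 0.0593). Some putative new miRNAs overlap, so that PN-151102661-5p, listed in early libraries alone, and PN-151102665-5p, listed in later ones alone, are neighbouring entries of 1 locus on chromosome 2 and no separate changes. PN-80868-5p (log2 fold change 6.96) and PN-80865-5p (−6.84) likewise share at least 16 bases, as do PN-14862190-5p (6.94) and PN-14862192-5p (−7.78). PN-85376639-3p, called lower, overlaps with PN-85376602-3p, which every early library listed. With overlapping entries joined, calls numbered 52, of which 44 were among the 54 by name.

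**Figure D2:**
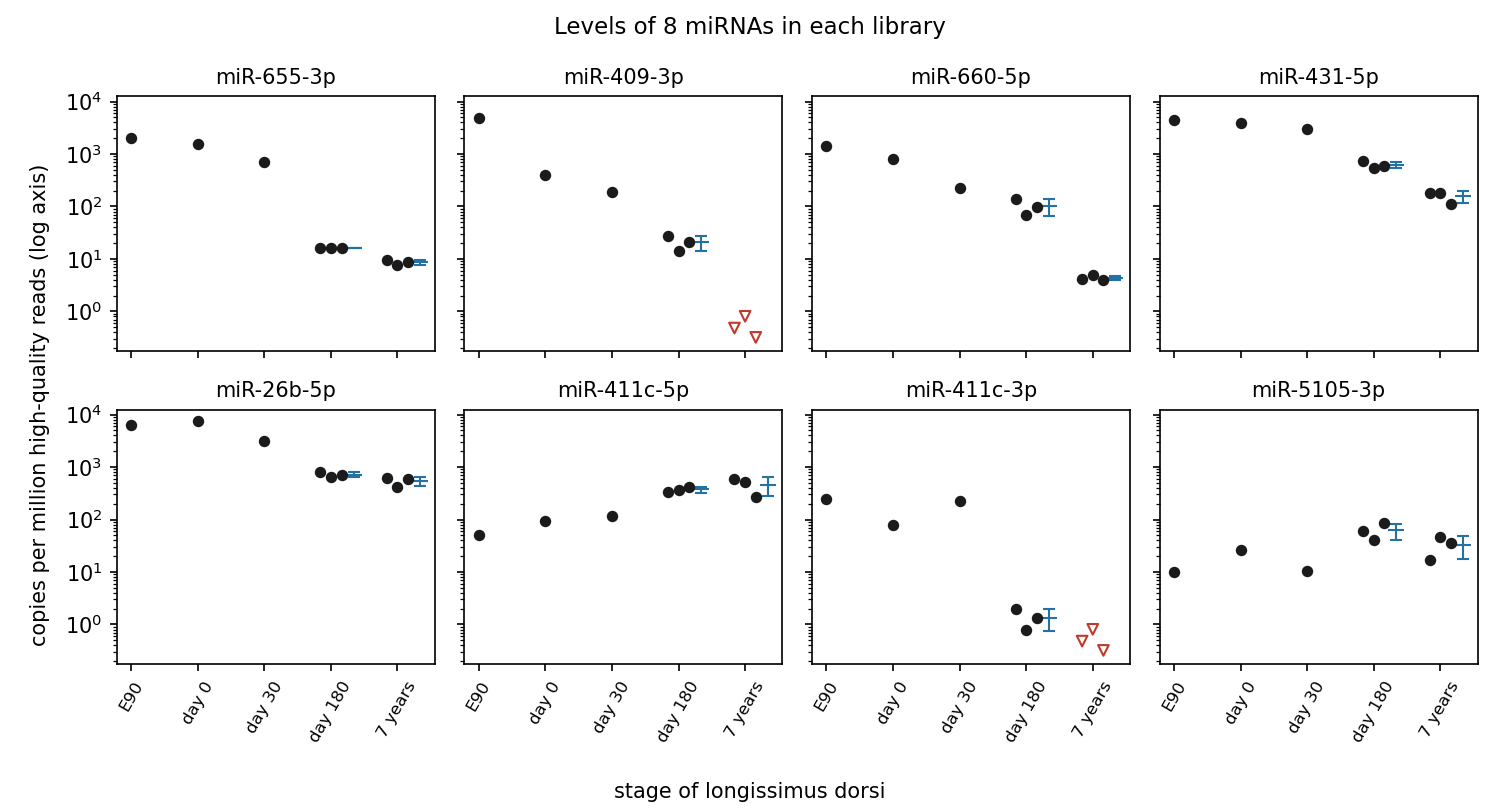
RPM (log axis) of single miRNAs in each library at each stage. Filled points are libraries, blue bars are mean ± SD over 3 libraries, and open red triangles mark the floor of 3 copies where a library lists no copies. miR-655-3p lies at 1994 at E90 and at 8.63 on average at 7 years, while miR-411c-5p goes from 51.0 to 462.

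E90, the fetal stage, was compared with day 180 as 1 library against 3, the lone library being assumed to vary like those of day 180 and 7 years. In the fetus 12 of 175 miRNAs were higher and 12 lower (edgeR, adjusted p under 0.05). On simulated counts 12.5% of the calls of this comparison were of unchanged miRNAs, more than this threshold allows. Higher were miR-409-3p at 4799 against 21 RPM (log2 fold change 5.39, SE 0.37, edgeR adjusted p = 0.000103), miR-655-3p at 1994 against 16.2 (4.47, SE 0.28) and miR-485-3p at 884 against 1.26 (6.98, SE 0.55). miR-376d-3p stood at 261 against 0.288, miR-412-5p at 659 against 1.77, miR-411c-3p at 246 against 1.35 and miR-660-5p at 1402 against 102 (1.34, SE 0.36, edgeR adjusted p = 0.0368). Lower were miR-411c-5p at 51.0 against 375 (−5.37, SE 0.64, edgeR adjusted p = 0.000444), miR-716a-3p at 3.57 against 38.8 (−5.94, SE 1.16), miR-5105-3p at 10.1 against 61.8 (−5.09, SE 0.92) and PN-7444591-3p at 6.15 against 134 (−6.88, SE 0.54).

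In the DLK1-DIO3 list 8 of 19 tested arms were higher at E90 and 1, miR-539-3p, was lower relative to the other miRNAs (10 and 1 when adjusted over the list alone). In RPM miR-539-3p was at 48.8 at E90 and 31.1 at day 180. limma camera, not fixed in advance for the single stages, gave an adjusted p = 1.2e-05 for the list and an adjusted p = 0.0444 with an estimated correlation. miR-26b-5p at 6477 against 715 and miR-431-5p at 4527 against 621 were not called relative to the other miRNAs (edgeR adjusted p = 0.0716 and 0.397), and both were called higher with DESeq2 size factors (0.000209 and 0.00116) and total reads (8.8e-06 and 4.1e-05). miR-26b-5p was also called higher by DESeq2's Wald test (0.00872), without a filter (0.0162), with empty cells set to 2 copies (0.0403), with joined putative new miRNAs (0.0369) and without 7 years replicate 2 (0.0329) or 3 (0.0483), and had a log2 fold change of −0.19 with conserved miRNAs alone. Scaling by total reads shifted log2 fold changes by 2.47, called 40 higher and 7 lower, and turned miR-539-3p to a log2 fold change of 0.65 without a call, as DESeq2 size factors did (0.13). DESeq2's Wald test called 16 higher and 27 lower, miR-539-3p lost its call without a filter (edgeR adjusted p = 0.198) and without day 180 replicate 1 (0.0791) and replicate 3 (0.0534), and miR-660-5p with conserved miRNAs alone (edgeR adjusted p = 0.686), without day 180 replicate 1 (0.0959), without day 180 replicate 3 (0.0837) and without 7 years replicate 1 (0.0501).

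At birth 12 of 175 miRNAs were higher and 7 lower than at day 180 (edgeR, adjusted p under 0.05, 1 library against 3). miR-655-3p stood at 1550 RPM against 16.2 (log2 fold change 4.44, SE 0.28, edgeR adjusted p = 1.2e-05), miR-376d-3p at 221 against 0.288 (7.40, SE 0.67) and miR-485-3p at 245 against 1.26 (5.46, SE 0.53). miR-539-3p at 513 against 31.1 (1.93, SE 0.34, edgeR adjusted p = 0.00506) was higher, and so was miR-26b-5p at 7522 against 715 (1.27, SE 0.22, edgeR adjusted p = 0.00506). Both calls ended with conserved miRNAs alone (edgeR adjusted p = 0.176 and 0.574, log2 fold changes 1.23 and 0.57). miR-411c-5p at 93.3 against 375 (−4.16, SE 0.59) and PN-7444591-3p at 2.01 against 134 (−8.13, SE 0.58) were lower. PN-868884-3p was listed with 804 copies at day 0 and in no other library, while PN-3335108-5p, whose sequence overlaps with it, was listed with 43, 54 and 14 copies at E90, day 0 and day 30 and with 9 and 5 copies in day 180 replicates 1 and 2.

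In the DLK1-DIO3 list 7 of 19 tested arms were higher at day 0 and none lower (9 when adjusted over the list alone). limma camera gave an adjusted p = 9.8e-05 and, with an estimated correlation, an adjusted p = 0.0589. The heart-muscle miRNA miR-208a-3p (chromosome 7, 81043844 to 81043943, minus strand) was listed at 21.7 RPM at day 0 and in no library of day 180, at least 75.3-fold higher, without a call (edgeR adjusted p = 0.142). It was called higher with DESeq2 size factors (0.0361), total reads (0.00250), no filter (0.0190), conserved miRNAs alone (0.000105), empty cells set to 2 copies (0.000471) and joined putative new miRNAs (0.0102). Scaling by total reads shifted log2 fold changes by 2.13 and called 40 higher and 3 lower, and DESeq2 size factors called 29 higher and 6 lower. miR-5105-3p and miR-716a-3p, called lower here (log2 fold changes −3.41 and −4.12), were not called with total reads. miR-5105-3p also lost its call without day 180 replicate 1 or 3 or 7 years replicate 2 or 3 (edgeR adjusted p from 0.0605 to 0.0708), miR-716a-3p without day 180 replicate 2 or 3 or 7 years replicate 2 (from 0.071 to 0.126), and miR-409-3p (log2 fold change 2.16) without day 180 replicate 1 (0.0503) and with conserved miRNAs alone (0.087).

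At day 30, 9 of 175 miRNAs were called higher and 6 lower than at day 180 (edgeR, adjusted p under 0.05, 1 library against 3). miR-655-3p stood at 721 RPM against 16.2 (log2 fold change 3.94, SE 0.28, edgeR adjusted p = 3.2e-05), miR-411c-3p at 223 against 1.35 (5.87, SE 0.60), miR-377-3p at 402 against 17.3 (3.07, SE 0.57) and miR-539-3p at 389 against 31.1 (2.13, SE 0.33). miR-411c-5p at 119 against 375 (−3.20, SE 0.56, edgeR adjusted p = 0.00831), miR-5105-3p at 10.6 against 61.8 (−4.08, SE 0.87) and PN-7444591-3p at 7.19 against 134 (−5.72, SE 0.51) were lower. miR-660-5p at 230 against 102 was not called (edgeR adjusted p = 0.646), nor was miR-208a-3p at 7.77 against no listed copy (edgeR adjusted p = 0.196). miR-208a-3p was called higher with total reads (0.00788), conserved miRNAs alone (0.000734), empty cells set to 2 copies (0.00284) and joined putative new miRNAs (0.0176), and miR-660-5p lower with the stricter filter (0.0295).

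In the DLK1-DIO3 list 5 of 19 tested arms were higher at day 30 and none lower (5 when adjusted over the list alone). limma camera gave an adjusted p = 5.1e-05 and, with an estimated correlation, an adjusted p = 0.0521. Scaling by total reads shifted log2 fold changes by 1.52, called 35 higher and 3 lower and turned the sign of miR-660-5p. Calls numbered 8, 9 and 6 without day 180 replicate 1, replicate 2 and replicate 3 and 10 without 7 years replicate 2, while miR-655-3p, miR-411c-3p, miR-539-3p and miR-411c-5p stayed called in each of these fits. miR-377-3p lost its call without day 180 replicate 2 (edgeR adjusted p = 0.0554) and replicate 3 (0.0508), and miR-5105-3p without day 180 replicate 1 (0.0657), day 180 replicate 3 (0.0574) and 7 years replicate 2 (0.0528). The comparisons of E90, day 0 and day 30 share the same 3 libraries of day 180, so that their calls are not independent of each other.

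Between the single libraries of E90, day 0 and day 30 there was no replicate and no test. From E90 to day 0, 21 of 32 conserved miRNAs with at least 100 copies in either library were lower and 11 higher after TMM scaling, and from day 0 to day 30, 17 of 25 were lower and 8 higher. The steepest drops before birth were in the DLK1-DIO3 cluster, miR-409-3p from 4799 to 405 RPM (log2 ratio −3.23, 95% counting interval −3.30 to −3.16) and miR-412-5p from 659 to 81.9 (−2.67, −2.83 to −2.51). miR-539-3p went the other way, from 48.8 to 513 (log2 ratio 3.73, 3.54 to 3.93), and miR-5105-3p from 10.1 to 25.7 (1.68, 1.196 to 2.19). After birth miR-377-3p went from 82.6 to 402 (2.89, 2.72 to 3.06) and miR-411c-3p from 78.3 to 223 (2.12, 1.94 to 2.31). miR-377-5p, the other arm of the mir-377 precursor, went from 68.9 to 4.31 (−3.39, −4.25 to −2.65), miR-485-3p from 245 to 28.2 (−2.51, −2.83 to −2.21) and miR-376d-3p from 221 to 24.2 (−2.59, −2.93 to −2.26). The intervals cover counting error alone and, as the exact intervals below, take copies as independent. By shares of total reads 9 were higher and 23 lower in the first step and 5 higher and 20 lower in the second, and miR-188-5p (TMM log2 ratio 0.41) turned to −0.20 in the second.

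A few miRNAs took most copies of both tables together. Ranked within each library, the 10 most abundant held 90.1% at E90 (exact 95% binomial interval 89.9 to 90.2), 87.6% at day 0 (87.4 to 87.8) and 85.7% at day 30 (85.3 to 86.0). They held 82.1% ± 0.619 (SD, n = 3) at day 180 and 87.7% ± 2.07 (SD, n = 3) at 7 years. The two-sided exact permutation p was 0.214 for the libraries up to day 30 against the later ones and 0.1, the smallest possible, for 7 years against day 180 (adjusted p = 0.257 and 0.15 over 6 relations). This ranking was chosen after seeing the data. miR-26b-5p was among these 10 in all 9 libraries, as was the entry of miR-431-5p, whose sequence is in doubt in 7 years replicates 2 and 3. Also among them were miR-409-3p, miR-655-3p and PN-1631-3p in the 3 early ones alone, and miR-411c-5p, PN-5388442-3p and PN-7444591-3p in the 6 later ones alone. The 10 with the highest mean RPM over all libraries, a mean to which the early libraries add most, held 87.1% at E90 (exact interval 86.9 to 87.2), 86.9% at day 0 (86.7 to 87.2) and 81.1% at day 30 (80.7 to 81.5). At day 180 they held 67.6% ± 1.30 (SD, n = 3) and at 7 years 72.2% ± 2.63 (SD, n = 3). As this choice favours the early libraries, its test of early against later libraries is not read as a result. Its p is still among the 6 relations over which the p-values above were adjusted. Within the conserved table alone the early libraries held 89.1%, 92.6% and 88.3% against 89.4% ± 0.431 at day 180 and 91.8% ± 3.49 at 7 years.

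Of the muscle-enriched list 2 of 8 members were measured, miR-208a and miR-1, the latter by a copy on chromosome 6 (miR-1-2-3p, 99481915 to 99482025, plus strand). The share of their 3 arms in the copies was 0 at E90, where none of the 3 was listed, 0.131% at day 0 (exact 95% interval 0.108 to 0.157) and 0.121% at day 30 (0.0882 to 0.163). At day 180 the share was 0.00746% ± 0.00741 (SD, n = 3) and at 7 years 0.00722% ± 0.0125 (SD, n = 3). The exact permutation p was 0.0833 for the early against the later libraries (adjusted p = 0.15) and 1 for 7 years against day 180. Neither member was called by edgeR with TMM in the 4 comparisons that tested them. For 7 years and for E90 against day 180 both lay at or under the floor on average, so a call was hardly possible there. miR-208a-3p was called higher at day 0 when adjusted over the list alone. Without the only library of E90 the permutation test of early against later libraries gave an exact p of 0.0357, the smallest possible there. miR-1a-2-5p, listed at the same interval as miR-1-2-3p, did not match the list by name and had 5, 40 and 6 copies at E90, day 0 and day 30. With it the share was 0.00367%, 0.178% and 0.138% there (exact p = 0.0476 for early against later libraries, not adjusted).

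Most markers of other cell types had no measured member, so how much of those cells the samples held cannot be read from these tables. The leukocyte miRNA miR-223-3p (X, 58752416 to 58752517), the only measured member of both the blood list (5 members) and the list of inflammation and ageing (6 members), was at 2.58, 5.59 and 4.03 RPM at E90, day 0 and day 30. It was at 4.49 ± 2.77 (SD, n = 3) at day 180 and 2.05 ± 1.57 (SD, n = 3) at 7 years (exact permutation p = 0.3 between these ages and 0.655 for early against later libraries). The list of epithelial and neural markers, with 4 of 13 members measured, summed to 11.7, 5.59 and 14.4 RPM at E90, day 0 and day 30. It summed to 1.78 ± 0.487 (SD, n = 3) at day 180 and 0.998 ± 0.168 (SD, n = 3) at 7 years (exact permutation p = 0.0119 and 0.1, as for the table sums). Relative to the other miRNAs, limma camera called no change of this list between 7 years and day 180 (adjusted p = 0.526, and 0.556 with an estimated correlation). Of the 3 arms tested there, miR-200b-3p was listed in no library of either age. miR-96-5p lay at or under the floor on average, so these arms carry little information on a change. None of the tested members of the list was called by edgeR with TMM in any of the 5 comparisons. For E90, day 0 and day 30 against day 180 the adjusted p of limma camera was 0.880, 0.336 and 0.171, and at E90 the median (−1.35) and the mean (1.17) of its log2 fold changes differed in sign. The lists of other myogenic miRNAs, of let-7, of the miR-17-92 cluster, of vessel and connective tissue and of miR-30 had no measured member.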

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

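The sequence columns, which no comparison used, were searched for most abundant sequences that share under 8 nt with the consensus of their arm. All tests in this part were chosen after the result was seen, and the biological differences between ages remain untested as explanations. Of 1399 cells 15 met this limit, in 9 arms.

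miR-431-5p, called lower at 7 years, had the same most abundant sequence TCCCTGAGACCCTAACTTGTGAA in 7 years replicate 2 (687 copies) and 7 years replicate 3 (1037 copies). It shares 4 nt with the consensus TGTCTTGCAGGCCGTCATGC of the arm and with its precursor, and it begins with the mature sequence of miR-125b-5p as generally known. miR-431-5p stood at 184.6 and 110.4 RPM in these libraries, and at 179.8 RPM in 7 years replicate 1. Whether the copies in those cells were counted from this sequence is open.

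Among cells with at least 100 copies, sequences from another part of the precursor were most abundant for miR-1983-3p at day 0 (134 copies) and day 30 (183 copies), for miR-5105-5p at day 30 (133 copies) and for PN-870046-5p at day 30 (482 copies). A further 9 cells with at most 81 copies had such a sequence, among them miR-1983-3p at E90 (81 copies) and in day 180 replicates 1 and 2 (21 and 19 copies). Of those with at least 100 copies, PN-870046-5p was called higher at day 30 than at day 180 (log2 fold change 2.02, edgeR adjusted p = 0.044). miR-1983-3p was called higher in the libraries up to day 30 than in the later ones (log2 fold change 3.31, edgeR adjusted p = 0.00622), and not without the only library of day 30 (0.0896). A most abundant sequence without a copy number stood in 3 cells, miR-6529-3p and miR-6529-5p in 7 years replicate 3 and miR-449b-5p at E90.

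The empty cells bear on the calls at 7 years. Of 44 conserved arms listed in every library of day 180, 13 were empty in every library of 7 years. Single missing entries exist, since 2 of 117 cells (1.71%) were empty although the other replicates predicted at least 20 copies, miR-6529-5p in 7 years replicate 3 (319 copies predicted) and miR-301a-3p in day 180 replicate 3 (259 copies predicted). Loss of single cells at that rate, each taken as independent, would leave 0.0002198 arms empty in all 3 libraries. That rate rests on cells with at least 20 predicted copies, which an arm empty in all 3 libraries cannot supply. Low arms such as miR-485-3p (1.26 RPM at day 180) may be lost at another rate, so the source of the 13 stays open. For miR-409-3p, copies under a minimum for listing are argued against, since its fall kept an adjusted p of 0.0001807 (edgeR) with empty cells at 2 copies (log2 fold change −5.70, SE 0.45). For miR-485-3p, miR-411c-3p and miR-412-5p such a minimum stays open, since 0 of these 3 calls remained at 2 copies, with log2 fold changes of −1.65 (SE 0.50), −1.75 (SE 0.56) and −2.14 (SE 0.77).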

How the results depend on the processing

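Setting empty cells to 2 copies, joining overlapping putative new arms, alone or with total reads, ranking the 10 most abundant within each library, taking miR-431-5p out of the DLK1-DIO3 list, adding miR-1a-2-5p to the myomiR list and leaving libraries out of sums and shares were chosen after seeing the data. The cause of the changes below was not tested. Over all alternatives, 1616 of 1869 values of named miRNAs kept direction and side of the threshold, 123 lost their call, 67 gained one, 50 changed sign and 13 single-library ratios moved beyond their counting interval, and miR-539-3p at E90 and PN-151102665-5p in early against later libraries were the only calls to change sign. Keeping every arm changed none. Depth limits day 30 and 7 years replicate 2 most, where a floor of 3 copies stands at 0.863 and 0.806 RPM.

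Calls for 7 years against day 180 (6) numbered 14 with total reads, 11 with conserved arms alone, 2 with the 6 libraries of these ages alone and 2 to 8 with single libraries left out. For early against later libraries (54) they numbered 71 without a filter, 24 with the strict filter, 22 with conserved arms alone and 44 to 61 with libraries left out. For E90 (24) they numbered 47 with total reads, 43 with the DESeq2 Wald test, 79 with empty cells at 2 copies, 48 with joined arms and 18 to 29 with libraries left out. For day 0 (19) they numbered 35 with DESeq2 size factors, 43 with total reads, 78 with empty cells at 2 copies, 35 with joined arms and 15 to 22 with libraries left out. For day 30 (15) they numbered 38 with total reads, 23 with the Wald test, 48 with empty cells at 2 copies, 34 with joined arms and 6 to 15 with libraries left out. From day 0 to day 30, 5 conserved arms were higher by shares of total reads in place of 8.

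The DLK1-DIO3 list had an adjusted camera p of 0.141 at 7 years with an estimated correlation, 0.1005 with empty cells at 2 copies, 0.0962 without miR-431-5p and 0.0183 to 0.144 with libraries left out. For early against later libraries it had p = 0.134 with an estimated correlation. The epithelial and neural list at 7 years ranged from an adjusted p of 0.404 to 0.927 with libraries left out and changed direction without 7 years replicate 1. The early minus late difference in the share of the 10 most abundant arms (15.1 points) became −0.597 with the conserved table as denominator and 2.88 (exact permutation p = 0.214) with the 10 ranked within each library. The myomiR share at 7 years minus day 180 (−0.000243 points) ranged from −0.00746 to 0.00344, and the early minus late one (0.0767) from 0.0533 to 0.119 with libraries left out. With miR-1a-2-5p these were 0.00746 and 0.0860 (exact p = 1 and 0.0476).

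Day 180 and 7 years share replicate numbers from different pigs. Deviations of same-numbered libraries correlated at −0.0363, −0.251 and −0.243, and not every library correlated best with its own number. With the replicate block, edgeR called 1 miRNA, limma camera gave the DLK1-DIO3 list an adjusted p of 0.357, and miR-655-3p had a log2 fold change of 0.046.

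Log2 fold changes that changed sign were of arms without a call, except miR-539-3p at E90 and PN-151102665-5p, which had 0.59 for early against later libraries with joined arms and total reads. At 7 years, total reads gave −0.81 for miR-141-3p, −0.40 for miR-26b-5p and −0.58 for miR-539-3p, and empty cells at 2 copies gave −0.52, −0.13 and −0.33. miR-141-3p had −0.0034 without a filter and −0.17 with conserved arms alone, and miR-655-3p 0.041 with the 6 libraries alone. With libraries left out, miR-141-3p ranged from −0.14 to 0.30, miR-223-3p from −1.03 to 0.35, PN-1631-3p from −8.30 to 5.49, miR-544-5p from −0.24 to 0.028 and miR-655-3p from −0.12 to 0.056. For early against later libraries miR-223-3p had 0.31 with total reads and 0.30 with joined arms besides, miR-544-5p −0.15 with the strict filter and −0.19 with conserved arms alone, and miR-141-3p −0.57 with conserved arms alone, −0.44 with a term per stage and −0.83 to 0.67 with libraries left out.

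At E90, DESeq2 size factors gave 0.13 for miR-539-3p and 0.40 for miR-141-3p, and total reads 0.65 and 0.89. miR-431-5p had −0.068 with the strict filter and −0.50 with conserved arms alone, where miR-26b-5p had −0.19 and miR-544-5p −0.093. At day 0 miR-141-3p had 0.18 with size factors and 1.34 with total reads, where miR-223-3p had 0.32. The strict filter gave −0.028 for miR-431-5p and −0.41 for miR-544-5p, conserved arms alone −0.16 and −0.55, and empty cells at 2 copies −0.022 for miR-544-5p. At day 30 miR-660-5p had 0.25 with size factors and 1.18 with total reads. The strict filter gave −0.0195 for miR-431-5p, −0.14 for miR-26b-5p and −0.77 for miR-544-5p, which had −0.40 with conserved arms alone, −0.18 and −0.097 without day 180 replicates 2 and 3, and −0.33 with empty cells at 2 copies.

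Sums of RPM of the conserved table, the putative new table, the DLK1-DIO3 list and the X-linked pair kept their direction with every library left out, and that of the chromosome 6 block did not. The ratio of early to later libraries ranged from 7.20 to 11.2 for the conserved table (9.16), from 3.83 to 6.13 for the putative new one (4.97), from 12.4 to 21.8 for the DLK1-DIO3 list (17.8, and 47.1 without miR-431-5p) and from 10.5 without E90 to 23.5 for the X-linked pair (16.1). For the chromosome 6 block (0.848) it ranged from 0.662 to 1.03, and was above 1 without E90 or without day 180 replicate 3. Without the conserved ones of the 10 most abundant arms of both tables, the conserved ratio was 8.20. For 7 years to day 180 it was 0.418 in place of 0.602.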

Other observations

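All tests in this part were chosen after the result was seen. The arms of single hairpins shifted between early and late libraries. Of the 8 hairpins with at least 20 copies in every library, mir-411c had 17.2%, 54.4% and 34.8% of its copies on the 5p arm at E90, day 0 and day 30 and 99.4% to 100% in the 6 later libraries (35.4 ± 18.6, SD, n = 3, against 99.8 ± 0.239, SD, n = 6). The two-sided exact permutation p was 0.0119, the smallest possible, and 0.0143 after adjustment over 6 hairpins. The other 2, mir-590 and mir-655, held too few copies of their rarer arm to be tested (under 3 expected). mir-5105 moved the other way, from 56.0%, 55.9% and 78.2% on the 5p arm to between 23.6% and 29.6% in the later libraries (exact p = 0.0119), and mir-716a had 33.3%, 15.1% and 11.9% against at most 4.88% (exact p = 0.0119). Both belong to a block on chromosome 6 of whose most abundant sequences 43.04% were 20 to 24 nt long, and at day 30 that of miR-5105-5p came from another part of the precursor, so whether these are shifts between hairpin arms is open. mir-539 had 28.9%, 5.33% and 0.442% against at most 1.14% (exact p = 0.0238, adjusted p = 0.0238). mir-26b and mir-431 kept over 96% of their copies on the same arm in each of the 9 libraries. mir-26b had a smaller shift that also gave an exact p of 0.0119, while for mir-431 the copies of 7 years replicates 2 and 3 are in doubt, since the most abundant sequence there does not match the precursor. These shares within a hairpin do not depend on the scaling of libraries.

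Some arms of the DLK1-DIO3 cluster that were abundant at E90 were listed in no library of 7 years. In RPM, miR-409-3p, at 4799 at E90, was at least 8961-fold lower at 7 years than at E90, miR-485-3p at least 1650-fold and miR-412-5p at least 1230-fold. With TMM factors of 4.25 at E90 and 0.375 to 0.446 at 7 years these bounds are smaller relative to the other miRNAs.

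The fall of the conserved table in RPM at day 180 and 7 years was set against 3 technical explanations. Copies left out under a minimum for listing are argued against, since with every empty cell at 2 copies the highest later library would reach 2515 RPM, and the lowest early library, at 9155 RPM as listed, stood 3.639-fold above it. A few abundant miRNAs as the whole cause are argued against too. Without the conserved ones of the 10 most abundant arms of both tables, the lowest early library exceeded the highest later one 3.133-fold (1140 against 364 RPM). A dilution of all small RNAs of the tables by 1 factor is argued against as the whole cause, since 10 arms, 3 of them conserved, were called higher in the later libraries by total reads with overlapping putative new arms joined, where the threshold allows 2.8 wrong calls among 56. Of the 3 conserved arms, miR-716a-3p and miR-5105-3p belong to the chromosome 6 block (edgeR adjusted p = 0.0407 and 0.0498). Only miR-411c-5p (0.00476) lies outside it. A dilution by other RNA in the 10 to 40 nt fraction, on top of changes of single miRNAs, stays open, and these calls set no limit on its size. By total reads, without joining, the median log2 fold change of early against later libraries was 2.62 over the 91 tested arms. Age itself, which was not tested apart from library preparation, stays open as well.

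The chromosome 6 block of mir-2887-2, mir-2904-3, mir-6087, mir-716a and mir-5105 stood at 138 ± 41.6 RPM (SD, n = 3) at day 180, not below the mean of the early libraries. Of its most abundant sequences 43.04% were 20 to 24 nt long, against 94.07% of those of the other conserved arms. This share does not tell cutting at varying places from a fixed length outside 20 to 24 nt. The most abundant sequence of miR-5105-3p was 17 nt long in every early and 16 nt in every later library. That of miR-2887-2-5p ranged from 16 to 27 nt. Whether the block holds pieces of a longer RNA stays open. Whether 1 library sets the level of day 180 cannot be told apart from a shared level, since without the highest library the mean was 113.8 RPM against 88.9 ± 39 (SD, n = 3) in the early libraries. A biological origin of the levels was not tested.

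For the counts of calls, other splits of the same libraries were fitted. For 7 years against day 180 the 10 splits are too few for a share under 0.05, with 6 calls in the real split and at most 1 in the others. For the early against the later libraries 1 of 84 splits, the real one, gave as many as 54 calls and the highest other split 1. That is the smallest share that 84 splits can give. Every other split mixes early and later libraries within a side, which widens the spread and lowers its calls. This count of splits therefore does not exclude chance.

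Putative new miRNAs overlapped among themselves. Of the 426 arms, 184 shared a stretch of 16 bases with another and fell into 70 groups, and in 26 of these groups no library listed more than 1 member. Joining them, which cannot raise the number listed in a single library, took it from 244 of 426 to 166 of 312.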
